A study of Mus musculus with 6 samples.

How the data were processed

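Gene expression was measured in RNA of mouse 344SQ tumours that had been sorted by flow cytometry into a CD133 high and a CD133 low fraction, with 3 arrays for each fraction and 6 in all. Per the labels' protocols, RNA was isolated with an Ambion kit, its quality was examined on a NanoDrop and a Bioanalyzer, and biotinylated cRNA was made by the array maker's protocol and hybridised to Affymetrix mouse arrays. The deposited values are log2 probe set values, as judged from the values themselves. Taken as powers of 2, those below 50 are multiples of 0.01 within rounding. On the log2 scale 1158 to 1297 probe sets per array are listed at exactly 0. The method by which the authors summarised and normalised the probes is not given in the sources used here. The labels name a smaller array of the same maker, whereas the deposited table holds 45101 probe sets of a larger one. The median log2 value per array lay between 6.60 and 6.77, and the 75th percentile between 8.48 and 8.56. The number of arrays limits the precision of all comparisons.

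The groups came from the sorted fraction stated for each sample. The labels number no replicates, so replicates were numbered in accession order and a shared number pairs no samples. Nothing in the labels says whether the 3 arrays of a fraction came from separate animals or sorts, so the p-values measure only the spread between these samples, which may be technical. No pair of arrays held the same values in more than 702 of the probe sets, and all 6 arrays were used as separate samples.

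The 64 control probe sets of the array were left out of all tests, which leaves 45037 probe sets. Gene names came from the annotation of the array platform. In it 34945 probe sets have 1 gene, 932 have several and 9160 are unnamed here. An Entrez gene of a RefSeq gene table matched 34741 of them, and no symbol changed in the update. Each of 18193 genes was represented by the probe set with the highest mean log2 value over the 6 arrays among those assigned to that gene alone.

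The fractions were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), by a linear model per probe set on the log2 values as deposited, moderated with a variance trend, two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. The floor of 16 planned for values on a linear scale did not apply, because the values were already log2. No covariate, added normalization or filter on dim probe sets was used. Differences are CD133 high minus CD133 low on the log2 scale. Errors of a difference are standard errors from the model, and errors of a mean are SDs over 3 arrays. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so none was used.

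There were 45 gene lists of pathways and cell type markers, with at least 5 measured genes in each. They held 1066 different genes, some in more than 1 list, of which 968 were measured. The lists were tested with camera from limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 45 lists. Camera with an estimated correlation and fry stand beside it. The count of list members past the threshold was taken over all probe sets and, separately, adjusted over the list alone. The choice of tests, lists, named genes and all alternatives except 3 was made before the data were examined.

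The named genes are Prom1, up to 10 genes per direction with the largest change among those past the threshold whose CD133 high arrays all lay on one side of the CD133 low arrays, the Notch receptors and ligands with Hes1, Hes5, Hey1, Hey2, Heyl and Nrarp, and up to 4 members of each list with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

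The steps were tested on simulated data with 200 of the 45037 probe sets changed. With the spread of all 6 arrays, 1.49% of probe sets changed by 1 on the log2 scale were recovered, 31.3% of those changed by 2 and 53.0% of those changed by 3, with 0 false calls. With the spread of the CD133 low arrays these shares were 25.4%, 67.2% and 77.3%, with 2 false calls. The simulated shift of 1 list was called, and 0 of the others were. Genes were drawn independently in this simulation, whereas the data gave estimated inter-gene correlations such as 0.303 (T and natural killer cell markers) and 0.709 (cytosolic ribosomal protein genes). It therefore cannot show how often camera at its preset correlation calls lists of correlated genes wrongly.

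The alternatives were quantile normalization, equal medians or 75th percentiles, leaving out the dimmest 50% or 25% of probe sets, a variance model without trend or with a robust trend, array weights, a test without moderation, thresholds of 0.1 or with a 2-fold change, the mean of a gene's probe sets, leaving out probe sets of shared sequence (_s_at and _x_at), the other list tests, and leaving out each array in turn. The 3 alternatives chosen after seeing the data were a floor of 5 on the log2 values, the mean of the hybridisation controls of each array as a covariate, and CD133 high replicate 1 alone against the CD133 low arrays. The mean of the poly-A controls of each array served as a covariate in 1 test of the closing section, also chosen after seeing the data.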

Results

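The tumours were grown under the skin of mice from 344SQ, a mouse lung adenocarcinoma line that spreads readily in syngeneic hosts. Their cells were separated on CD133, a cell-surface glycoprotein encoded by Prom1 and used as a marker of progenitor-like cells, and RNA of the CD133 high and CD133 low fractions was measured on 3 arrays each. The study's title concerns a tumour cell population prone to metastasis that responds to Notch inhibition, so the comparison of the fractions asks which genes, and which Notch pathway genes, set these cells apart. The labels name no sample given a Notch inhibitor.

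The CD133 high arrays differed among themselves. CD133 high replicate 1 correlated more closely with the CD133 low arrays, at a mean Spearman rho of 0.973, than with the other CD133 high arrays, at 0.931, taken across probe sets, which are not independent replicates. On the first principal component, with 46.2% of the variance, the CD133 low arrays lay at −70.8, −77.1 and −59.1, CD133 high replicate 1 at −52.4, and CD133 high replicates 2 and 3 at 126 and 133. The bacterial BioB, BioC and BioDn hybridisation controls, which are added to each sample before hybridisation, averaged 10.19, 10.51 and 10.22 on the CD133 low arrays and 10.38, 11.29 and 11.04 on CD133 high replicates 1, 2 and 3. The poly-A controls, which are added to the RNA before labelling, averaged 12.03, 12.32 and 11.64 on the CD133 low arrays and 11.35, 11.67 and 10.40 on CD133 high replicates 1, 2 and 3, so they did not set replicates 2 and 3 apart from replicate 1. The Gapdh control probe set at the 3' end exceeded the one in the middle of the transcript by −0.09, −0.09 and −0.07 on the CD133 low arrays and by −0.13, 0.44 and 0.46 on the CD133 high arrays in the same order.

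**Figure D1:**
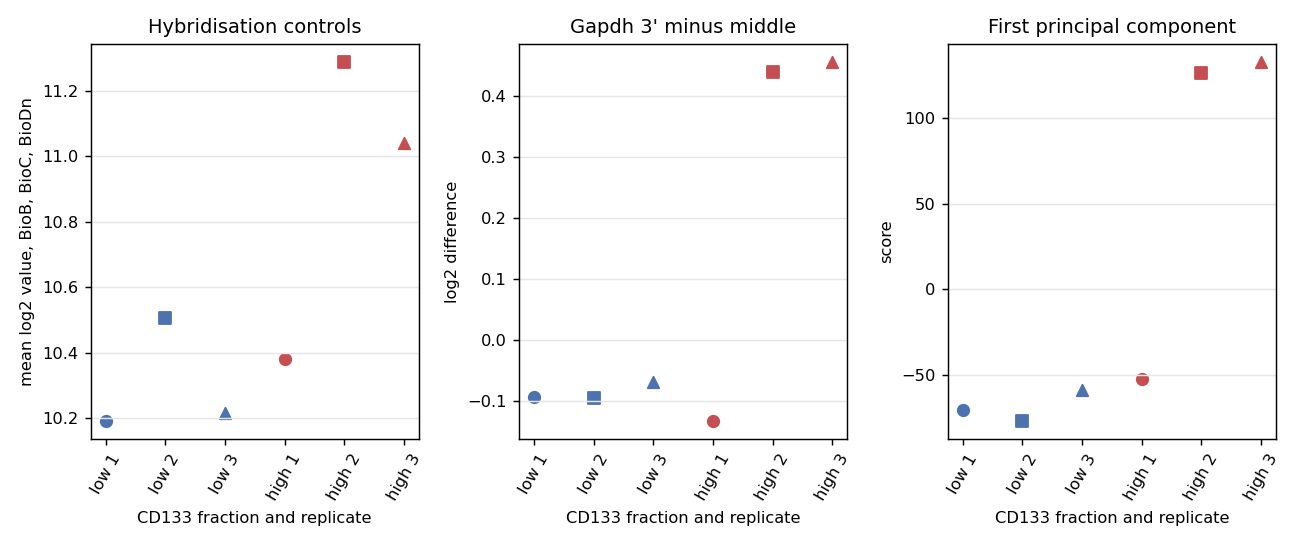
Each point is 1 array, in blue for CD133 low and red for CD133 high; the panels plot the mean log2 value of the hybridisation controls, the log2 difference between the 3' and middle Gapdh control probe sets, and the score on the first principal component. CD133 high replicates 2 and 3 lie above the other 4 arrays in each panel, at 11.29 and 11.04 for the hybridisation controls.

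Prom1, the gene of the sorted antigen, had a log2 value of 6.61 ± 0.203 in the CD133 high fraction and 5.82 ± 0.294 in the CD133 low fraction (SD, n = 3 arrays each). All 3 CD133 high arrays lay above all 3 CD133 low arrays, with the highest value, 6.805, in CD133 high replicate 1. The difference of 0.79 (SE 0.26) did not pass the threshold, with an adjusted p of 0.297 from limma. Prom1 serves here to check the labels and is no finding.

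Lymphocyte genes fell in the CD133 high fraction. Cd79b and Cd79a, which encode the signalling chains of the B-cell antigen receptor, had log2 changes of −4.10 (SE 0.26, adjusted p = 0.0114) and −3.06 (SE 0.23, adjusted p = 0.0168). The immunoglobulin segments Ighv14-2, Igkv6-20 and Igkv6-14 fell as well, with log2 changes of −3.65, −3.43 and −3.38. So did Cxcr5, the chemokine receptor that guides lymphocytes to B-cell follicles (−3.25), Xcl1, a chemokine made by activated T and natural killer cells (from 7.70 to 4.61, in the dim range), and Fcmr, the receptor for the Fc part of IgM (−3.01). The call of Xcl1 was lost with values below 5 set to 5 and with no variance trend (limma, adjusted p = 0.0750 and 0.0612). Cd79b stood at 5.65 ± 0.186 in the CD133 high fraction and 9.75 ± 0.442 in the CD133 low fraction, and Igkv6-14, among the brighter of these genes, at 9.55 ± 0.823 and 12.94 ± 0.191.

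The largest fall was that of Mak, a protein kinase first described in male germ cells, from 11.22 ± 0.250 to 4.77 ± 0.482, in the dim range (adjusted p = 0.0045), so only a lower bound of its size can be given. With values below 5 set to 5, Mak had a log2 change of −6.11 (adjusted p = 0.0117, range over all alternatives 3.40e-04 to 0.154). The other probe set of Mak differed by −0.18 (adjusted p = 0.845) and stood at 5.39 in the CD133 low fraction. The transcript 1700052I22Rik stood at a mean of 3.95 in the CD133 high fraction, in the dim range, against 7.46 in the CD133 low fraction (adjusted p = 0.0374), so no size of change is given for 1700052I22Rik. Its other probe set differed by 0.17 (adjusted p = 0.834). The call of 1700052I22Rik was lost with values below 5 set to 5 and with the mean of its probe sets (limma, adjusted p = 0.164 and 0.137).

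At their brightest probe sets 4 genes rose. Gldc, the glycine decarboxylase of the mitochondrial glycine cleavage system, rose by 2.83 (SE 0.29, adjusted p = 0.0269), from 5.23 ± 0.241 to 8.07 ± 0.438. Sema3e, a secreted semaphorin that signals through plexin D1, rose by 1.75 (SE 0.19, adjusted p = 0.0361), and Spats2 rose by 1.62 (SE 0.17, adjusted p = 0.0337). Lrrc36, which encodes a leucine-rich repeat protein, was near the bottom of the scale on the CD133 low arrays, at 0.49, 0.52 and 0.33, and stood at 8.16, 11.76 and 11.64 on the CD133 high arrays (adjusted p = 0.0204), so no fold is given for it. Dimmer probe sets of Incenp and Tmem241, chosen after their values were seen, rose as well (adjusted p = 0.0186 and 0.037). They rose from means of 1.24 and 1.74 near the bottom of the scale. The brightest probe sets of Incenp and Tmem241 differed by 0.37 and −0.42 (adjusted p = 0.425 and 0.33).

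**Figure D2:**
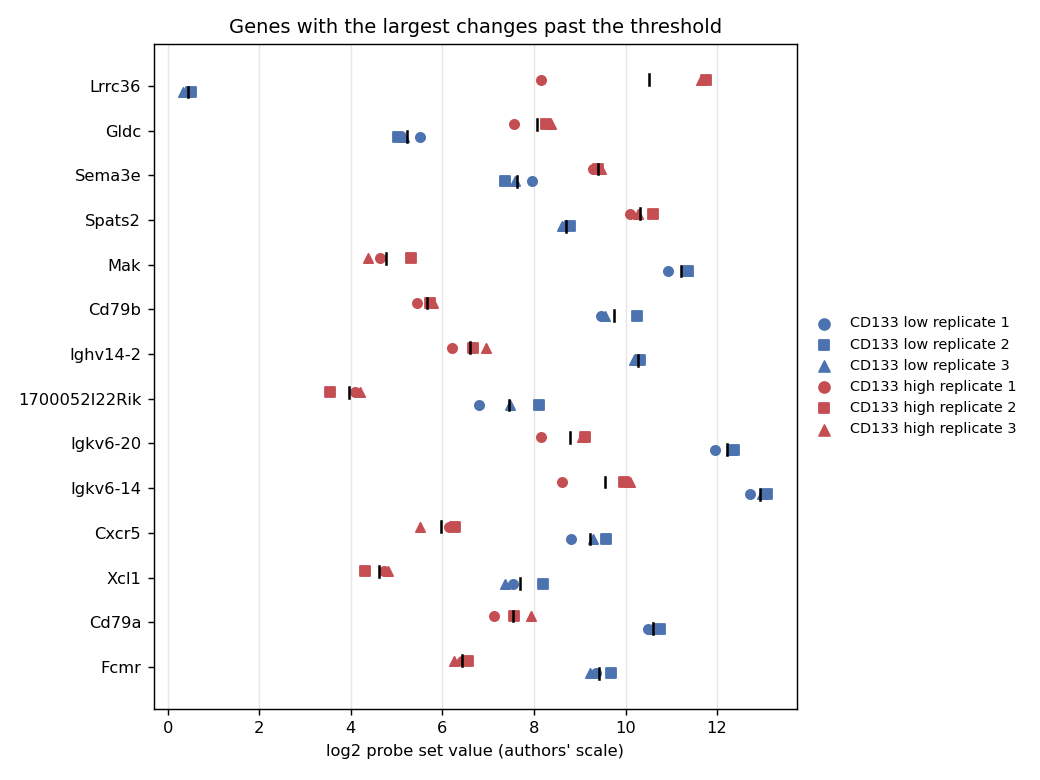
Each point is the log2 value of 1 array for the genes with the largest changes past the threshold, in blue for CD133 low and red for CD133 high, with the mean of each fraction as a black bar. For each gene the 3 CD133 high arrays lie apart from the 3 CD133 low arrays, most widely for Lrrc36 and Mak, whose means were 11.22 in the CD133 low fraction and a dim 4.77 in the CD133 high fraction.

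In all, 7 of the 45037 probe sets rose and 75 fell. By gene these were 4 and 42 of 18193. Of the 82 probe sets, 16 named an immunoglobulin or T-cell receptor gene or segment, 11, each of them lower, are unnamed here, and 3 named several genes. All 82 had fractions that did not overlap, as did 20.8% of all probe sets, against 10% by chance. When CD133 high replicate 1 was left out, 4277 probe sets rose and 5326 fell, the 82 among them. Leaving out any other single array left 0 probe sets higher and at most 1 lower in limma, with 1580 to 2618 higher and 1409 to 2407 lower at an unadjusted p under 0.05.

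Among markers of T and natural killer cells, 5 of 24 genes fell, 18 when adjusted over the list alone, and the median log2 change was −1.21. Cd3e and Cd3g, chains of the T-cell receptor complex, changed by −2.34 and −2.81, Cd8b1, a chain of the CD8 co-receptor, by −2.42, and Cd5, a regulator of T-cell receptor signalling, by −2.30. Camera gave an adjusted p of 2.95e-14, and an adjusted p = 0.537 with an estimated correlation. Against the mean of the CD133 low arrays, the list median was −0.73 in CD133 high replicate 1 and −1.65 in each of CD133 high replicates 2 and 3, the arrays with the higher hybridisation controls of 11.29 and 11.04.

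Of 14 B-cell and plasma cell markers, 3 fell, Cd79b, Cd79a and Ms4a1, which encodes CD20 (−2.81). When adjusted over the list alone 7 fell, and the median change was −1.17. Camera gave an adjusted p of 1.22e-04, and an adjusted p = 0.624 with an estimated correlation. Here CD133 high replicate 1 had the lowest list median, −1.74, against −0.74 and −0.79 in replicates 2 and 3.

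Other leukocyte markers were divided. Pan-leukocyte genes fell as a list, with a median of −0.64 over 23 genes (adjusted p = 0.0084), although 0 of the genes fell singly, also adjusted over the list alone, where 7 had an unadjusted p under 0.05 in limma. The list median was 0.04 in CD133 high replicate 1 and −0.88 and −0.96 in replicates 2 and 3, and the call was lost with an estimated correlation (adjusted p = 0.757). With CD133 high replicate 1 alone set against the CD133 low arrays the direction turned, with a median of 0.04. Dendritic cell markers fell as a list (13 genes, median −0.63, adjusted p = 0.0084, and adjusted p = 0.601 with an estimated correlation), with Ccr7, a homing receptor of lymphocytes and mature dendritic cells, at −2.67 (adjusted p = 0.0633). Mast cell and basophil markers did so too (9 genes, median −1.08, adjusted p = 0.0142, and adjusted p = 0.601 with an estimated correlation), with the proteases Cma1 at −1.43, Tpsb2 at −1.08 and Cpa3 at −1.28. On CD133 high replicates 1, 2 and 3 the list medians were −0.27, −0.35 and −0.78 for dendritic cell markers and −0.48, −1.16 and −1.49 for mast cell and basophil markers, whose call was lost in CD133 high replicate 1 alone (adjusted p = 0.16) and with the hybridisation controls as a covariate (adjusted p = 0.11), in a range of 0.0032 to 0.601 over all alternatives. No gene of these 2 lists fell singly in limma, where 4 dendritic and 7 mast cell markers had an unadjusted p under 0.05, whereas adjusted over the list alone 4 dendritic cell markers fell and, of the mast cell list, 5 fell and 1 rose. The 26 macrophage and monocyte markers had a median of −0.10 (adjusted p = 0.524), with list medians of 0.09, −0.26 and −0.19 on the 3 CD133 high arrays. The 14 neutrophil markers had a median of −0.24 (adjusted p = 0.365), with list medians of 0.69, −0.79 and −0.92 on CD133 high replicates 1, 2 and 3.

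Antigen presentation genes fell as a list, with a median of −0.91 over 17 genes (adjusted p = 5.67e-04, and adjusted p = 0.537 with an estimated correlation). H2-Ob, a chain of the H2-O molecule that tunes peptide loading of class II, was the single member to fall across the array (−1.96, SE 0.16, adjusted p = 0.0186), and 8 fell adjusted over the list alone. The class I regulator Nlrc5 (−1.19), the peptide transporter Tap1 (−1.03) and H2-Oa (−2.37) had an adjusted p of 0.11, 0.11 and 0.112. The abundant class II genes H2-Aa, H2-Ab1 and Cd74 differed by −0.18, 0.07 and 0.29, and B2m by −0.01, with none past the threshold; these were chosen after their values were seen. The list medians were −0.17, −0.75 and −0.98 on CD133 high replicates 1, 2 and 3. With the hybridisation controls as a covariate the list median was −0.10, with an adjusted p of 0.0064 in a range of 3.34e-05 to 0.537 over all alternatives.

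**Figure D3:**
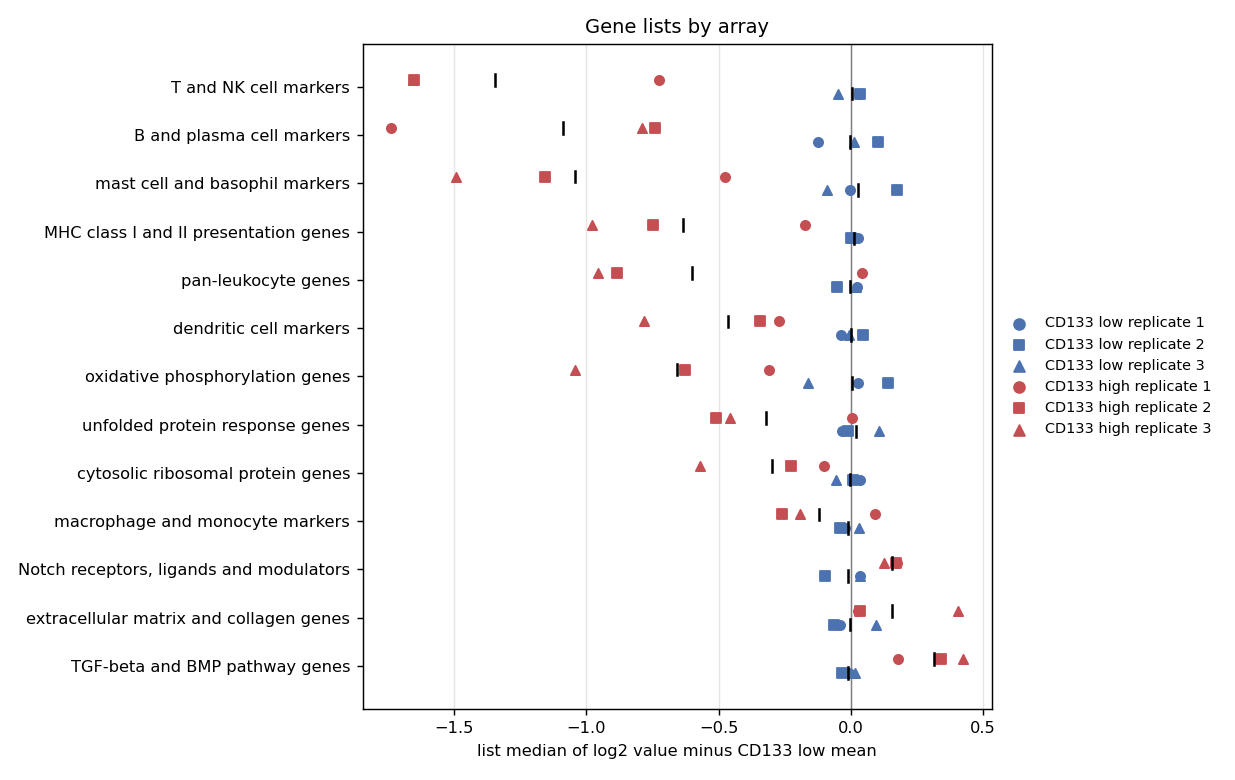
Each point is the median over a gene list of the log2 value of 1 array minus the CD133 low mean, in blue for CD133 low and red for CD133 high, with the mean of each fraction as a black bar. The T and natural killer cell list lies at −0.73, −1.65 and −1.65 on CD133 high replicates 1, 2 and 3, and the macrophage list at 0.09, −0.26 and −0.19.

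Genes of energy and protein production were lower as lists. Oxidative phosphorylation genes had a median change of −0.63 over 36 genes (adjusted p = 6.66e-10, and adjusted p = 0.624 with an estimated correlation), among them the complex I subunits Ndufs3 (−0.71) and Ndufs8 (−0.78) and the cytochrome Cyc1 (−0.85). No member passed across the array in limma, where 22 had an unadjusted p under 0.05, and 12 fell adjusted over the list alone. Genes of cytosolic ribosomal proteins fell as a list, with a median of −0.27 over 26 genes (adjusted p = 4.35e-04, and adjusted p = 0.757 with an estimated correlation), with 0 members past the threshold across the array or adjusted over the list alone in limma and 4 at an unadjusted p under 0.05. Genes of the unfolded protein response fell as a list, with a median of −0.30 over 23 genes (adjusted p = 0.0199, and adjusted p = 0.757 with an estimated correlation). Its members Creld2 (−2.03), Pdia4 (−1.87) and Edem1 (−1.76), which act in folding or disposal of proteins of the endoplasmic reticulum, did not pass across the array, nor did any other member in limma, where 8 had an unadjusted p under 0.05, and 5 fell adjusted over the list alone. On CD133 high replicates 1, 2 and 3 the list medians were −0.31, −0.63 and −1.04 for oxidative phosphorylation, −0.10, −0.23 and −0.57 for ribosomal proteins, and 0.00, −0.51 and −0.46 for the unfolded protein response, beside Gapdh 3' to middle differences of −0.13, 0.44 and 0.46. The unfolded protein response lost its call with quantile normalization (adjusted p = 0.0896) and without CD133 low replicate 3, CD133 high replicate 2 or CD133 high replicate 3 (adjusted p = 0.0529, 0.0537 and 0.0665), in a range of 0.0029 to 0.873 over all alternatives. Its median turned to 0.02 with the hybridisation controls as a covariate and to 0.0043 in CD133 high replicate 1 alone, where that of ribosomal proteins lost its call (adjusted p = 0.129).

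Extracellular matrix and TGF-beta and BMP pathway genes rose as lists. The matrix list had a median of 0.21 over 38 genes (adjusted p = 0.0175, and adjusted p = 0.757 with an estimated correlation), with Nid1, a basement membrane protein, at 0.71, Eln, which encodes elastin, at 1.41, and Timp1, a protease inhibitor, at −0.67. No member passed across the array or adjusted over the list alone in limma, and 5 had an unadjusted p under 0.05. On CD133 high replicates 1, 2 and 3 the medians of the matrix list were 0.03, 0.03 and 0.41. On the CD133 low arrays they were −0.04, −0.06 and 0.10, so the rise of this list rested on CD133 high replicate 3. Its call was lost without CD133 high replicate 3 (median 0.08, adjusted p = 0.233) and without CD133 low replicate 2 (adjusted p = 0.0583), within a range of 0.0015 to 0.757 over all alternatives. The TGF-beta and BMP list had a median of 0.29 over 26 genes (adjusted p = 0.0407, and adjusted p = 0.537 with an estimated correlation). Its member Bmp2, a secreted bone morphogenetic protein, stood at 9.73 ± 0.109 against 8.45 ± 0.268, a difference of 1.29 (SE 0.18) whose adjusted p of 0.0699 missed the threshold; Bmp2 alone rose adjusted over the list alone. The call was lost under 8 of 21 alternatives. Leaving out CD133 high replicate 1, CD133 high replicate 3 or CD133 low replicate 2 ended it, with an adjusted p of 0.109, 0.0665 and 0.0552, in a range of 0.0192 to 0.537 over all alternatives.

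The 34 remaining lists did not pass, with medians between −0.26 and 0.39 and a smallest adjusted p of 0.0526. Epithelial genes (34 genes) had a median of 0.08 and mesenchymal genes (25 genes) of 0.17, with adjusted p of 0.524 and 0.293. Markers of endothelium and of fibroblasts had medians of 0.02 and 0.12 (adjusted p = 0.524 and 0.665). Stem and progenitor cell genes, a list that holds Prom1, had a median of 0.19 over 27 genes (adjusted p = 0.0783), and adjusted over the list alone 5 rose and 1 fell, with Itga6, a laminin receptor chain, at 0.87, the retinaldehyde dehydrogenase Aldh1a3 at 0.96 and Lgr5, an R-spondin receptor, at 0.71. In MAPK pathway output genes, which include the feedback inhibitors Spry2 (1.12), Spry4 (0.61) and Dusp6 (0.56), the median was 0.23 over 21 genes (adjusted p = 0.0526). With an estimated correlation 0 of the 45 lists passed, the smallest adjusted p being 0.537, and 2 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way without reference to other genes, called 8 lists, 3 of them shared with camera's 11. Those shared were T and natural killer cell markers, antigen presentation genes and TGF-beta and BMP genes (fry, adjusted p = 0.0243, 0.0328 and 0.0409). The rest of camera's lists did not pass in fry, among them oxidative phosphorylation genes (adjusted p = 0.165) and B and plasma cell markers (adjusted p = 0.0565). Those called by fry alone included stem and progenitor cell genes (adjusted p = 0.0086) and MAPK pathway output genes (adjusted p = 0.0409). Cholesterol synthesis, integrin and adhesion, and pericyte and smooth muscle lists made up the rest (adjusted p = 0.0368, 0.0368 and 0.0433). The pericyte and smooth muscle list had a median of −0.0057, with 7 positive and 9 negative differences.

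Among Notch ligands and receptors 1 probe set, of Jag1, passed the test, and no gene did at its brightest probe set. Jag1, a ligand of the Notch receptors, had a log2 value of 11.82 ± 0.0746 against 10.82 ± 0.259 at its brightest probe set, a difference of 0.998 (SE 0.17, adjusted p = 0.125). This difference passed without CD133 high replicate 1 (adjusted p = 0.0159) and with array weights (adjusted p = 0.037), in a range of 0.0159 to 0.545 over all alternatives. A second probe set of Jag1, chosen after its value was seen, rose by 1.42 (SE 0.17, adjusted p = 0.042), and the remaining one differed by 0.18 (adjusted p = 0.806). The call of the second was lost under 10 of 18 alternatives, with adjusted p between 0.0061 and 0.308 over all of them. It was lost when any array other than CD133 high replicate 1 was left out. Other losses came with no variance trend (adjusted p = 0.128) and in the test without moderation (adjusted p = 0.232). The ligand Dll1 differed by 0.98 (SE 0.21, adjusted p = 0.209), Jag2 by 0.73 (SE 0.21, adjusted p = 0.297), Dll4 by 0.29 (adjusted p = 0.426) and Dll3 by 0.01 (adjusted p = 0.996). Among the receptors Notch2 differed by 0.65 (SE 0.25, adjusted p = 0.304), with its CD133 high values at 11.53, 12.40 and 11.75 against 11.24 ± 0.153 in the CD133 low fraction, while Notch1, Notch3 and Notch4 differed by −0.25, 0.10 and 0.13. At the brightest probe sets of Jag1, Dll1, Jag2, Dll4 and Notch2 all 3 CD133 high arrays lay above the CD133 low arrays. Over all genes, 23.6% had fractions that did not overlap, in either direction. The fractions overlapped at a dimmer probe set of Jag1, Jag2, Dll4 and Notch2. At a dimmer probe set of Notch1 (−0.37) all CD133 high arrays lay below the CD133 low arrays. Without CD133 high replicate 1, Dll1 (adjusted p = 0.0095, range over all alternatives 0.0095 to 0.646) and Notch2 (adjusted p = 0.0449, range 0.0449 to 0.894) passed, as Dll1 did with array weights (adjusted p = 0.0351). Without CD133 high replicate 1, only replicates 2 and 3 stood for the CD133 high fraction, the arrays with higher hybridisation controls and Gapdh 3' to middle differences. Calls of this kind were common, because in that setting limma called 2131 of the 18193 genes higher and 2659 lower. With array weights it called 1075 higher and 1399 lower. In CD133 high replicate 1 alone Dll1 differed by 0.65, Dll4 by 0.16 and Notch2 by 0.28, and with the hybridisation controls as a covariate Dll4 differed by 0.13 and Notch2 by 0.27. Without CD133 high replicate 2 Notch2 differed by 0.40 and Dll4 by 0.18, and with the mean of a gene's probe sets Jag2 differed by 0.37 and Dll4 by 0.10.

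Of 26 Notch receptors, ligands and modulators, none passed across the array at its representative probe set and 2 rose adjusted over the list alone, with a median change of 0.14; 5 had an unadjusted p under 0.05 in limma. Camera gave an adjusted p of 0.0526, which missed the threshold, an adjusted p = 0.601 with an estimated correlation, and fry 0.0683. The list passed under 9 of 21 alternatives, such as quantile normalization (adjusted p = 0.0201), in a range of 0.0052 to 0.601 over all of them. It passed without CD133 low replicate 3, CD133 high replicate 2 or CD133 high replicate 3, with an adjusted p of 0.0402, 0.0424 and 0.0294. It did not pass with any other single array left out, CD133 high replicate 1 among them, nor with array weights.

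The 22 Notch target genes and nuclear effectors had a median change of 0.09 and a mean of −0.02 (camera, upward, adjusted p = 0.467). None passed across the array in limma, where 6 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone, which was Gata3, a transcription factor also central to T-cell development, at −1.72 (SE 0.30, adjusted p = 0.129). Hes1 and Hey1, transcriptional repressors induced by Notch, differed by 0.58 (SE 0.21, adjusted p = 0.30) and 0.93 (SE 0.24, adjusted p = 0.272), with all CD133 high arrays above the CD133 low arrays. Hey1 passed without CD133 high replicate 1 (1.14, adjusted p = 0.0103) and with array weights (adjusted p = 0.0356), in a range of 0.0103 to 0.693 over all alternatives. Calls were common in both settings, with 2131 of 18193 genes higher and 2659 lower without CD133 high replicate 1. That setting left replicates 2 and 3, set apart by hybridisation controls and Gapdh 3' to middle differences, as the CD133 high arrays. With array weights 1075 were higher and 1399 lower. In CD133 high replicate 1 alone Hey1 differed by 0.52 and Hes1 by 0.34, and with the hybridisation controls as a covariate by 0.60 and 0.33. Hey2 stood at 4.78, 6.51 and 6.46 on CD133 high replicates 1, 2 and 3 against a dim 4.85 ± 0.0647 in the CD133 low fraction (adjusted p = 0.341). It passed without CD133 high replicate 1 (adjusted p = 0.0114) and with array weights (adjusted p = 0.0476), in a range of 0.0114 to 1 over all alternatives, and turned to −0.0668 in CD133 high replicate 1 alone. Heyl and Nrarp differed by 0.05 and 0.22 (adjusted p = 0.909 and 0.55), and Hes5 was dim in both fractions, at 3.84 and 4.36, so no direction is given for Hes5 (adjusted p = 0.622). A dimmer probe set of Heyl differed by −1.18 (limma, adjusted p = 0.297), with all CD133 high arrays below the CD133 low arrays. The remaining probe set of Heyl differed by 0.42 (adjusted p = 0.362), with all CD133 high arrays above.

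**Figure D4:**
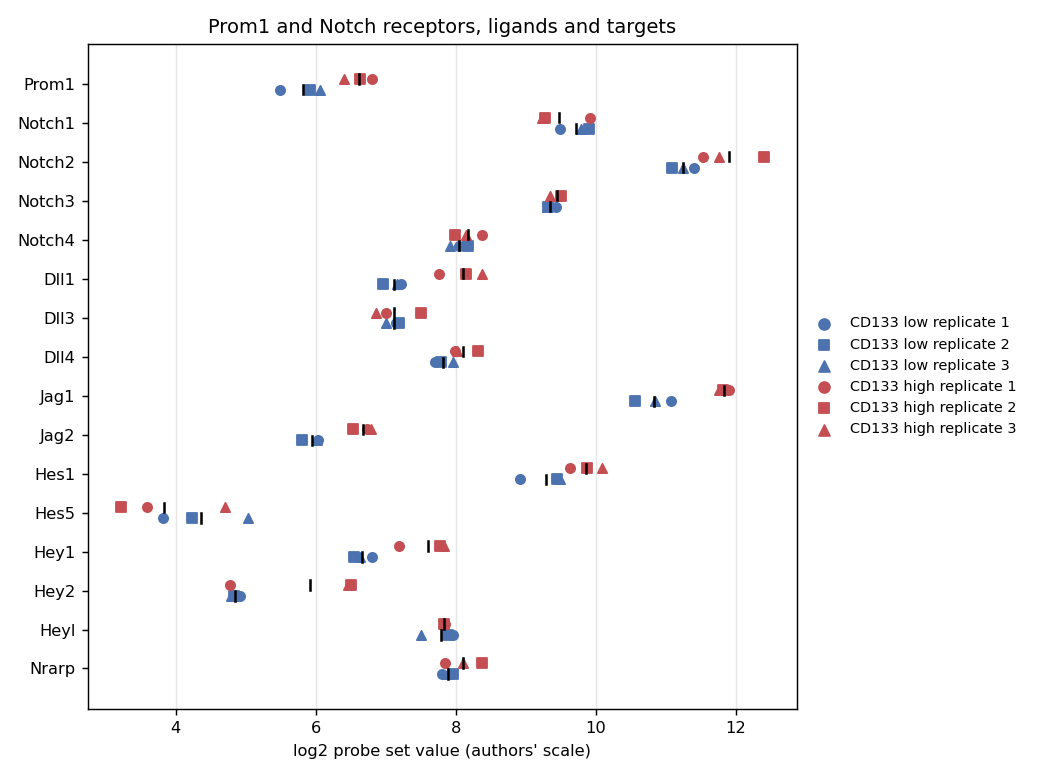
Each point is the log2 value of 1 array for Prom1 and for Notch receptors, ligands and targets, in blue for CD133 low and red for CD133 high, with the mean of each fraction as a black bar. At the brightest probe set of each gene, plotted here, the fractions lie apart for Jag1, at 11.82 against 10.82, and for Dll1 and Jag2. They overlap for Notch1, Dll3 and Heyl.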

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

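The tests of a wrong label, of a mixture and of the causes of the lower lymphocyte genes were chosen only after the result was seen; the test of probe sets within genes and the count of other splits were planned before their results.

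The hybridisation controls, which the comparison of the fractions does not use, carried a signal of their own. Their mean log2 value was 10.90 ± 0.468 in the CD133 high fraction and 10.30 ± 0.175 in the CD133 low fraction (SD, n = 3 arrays each), a difference of 0.60 that rests on CD133 high replicates 2 and 3.

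CD133 high replicate 1 lay closer to the CD133 low arrays than to the other CD133 high arrays. Its T and natural killer cell list median of −0.73 lay below the CD133 low arrays, which spanned 0.08. This argues against a wrongly labelled sample like those CD133 low arrays. Its B and plasma cell list median of −1.74 lay below all other arrays. A mixture of RNA like theirs would lie between if all arrays were labelled alike. The differences between probe sets given below leave that in doubt, so this median cannot decide about such a mixture. Both lists were picked after their values on these arrays were seen, and the CD133 low arrays may be technical repeats. A wrongly labelled sample from another tumour or sort, or a mixed sample, is therefore not excluded. A difference in RNA amplification or labelling may account for part of the distance: across 2819 genes with 2 bright probe sets, the difference between probe sets of the same gene, against the CD133 low mean, correlated at r = 0.89 between CD133 high replicates 2 and 3 (0.872 when each was set against a different CD133 low array), and at 0.131 and 0.156 between replicate 1 and these. The SD of this difference over genes was 0.884 and 0.878 on CD133 high replicates 2 and 3 and 0.277 on replicate 1. It was 0.147, 0.147 and 0.174 on the CD133 low arrays. On replicates 2 and 3 the probe sets of a gene thus moved apart more than on the other arrays. The mean of the 2 probe sets deviated with an SD of 0.598 and 0.651 on replicates 2 and 3. A biological difference between the sorted samples stays open and untested, and its share cannot be read from these data.

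T-cell and B-cell genes were lower in all 3 CD133 high arrays. A trend in labelling that the poly-A controls follow is argued against as the whole cause by the T and natural killer cell list, whose median was −1.09 with these controls as a covariate (median SE of its members 0.37), and the authors' scaling by −1.195 after quantile normalization (0.285). Fewer leukocytes of every kind would lower macrophage genes alike, but the T and natural killer cell median lay at least 0.82 below that of macrophages in each CD133 high array (gap of −0.82 in replicate 1). Other leukocyte lists went partly with fewer leukocytes, with pan-leukocyte genes at 0.04, −0.88 and −0.96 and neutrophil markers at 0.69, −0.79 and −0.92 on CD133 high replicates 1, 2 and 3, so a lower share of further leukocyte types in replicates 2 and 3 stays open. A smaller share of lymphocytes in the CD133 high gate is a candidate explanation that stays open, as does any difference in amplification or labelling that the poly-A controls do not follow; of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 82 probe sets and the highest other gave 0 (limma; up to 6152 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.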

How the results depend on the processing

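Of the alternatives, a floor of 5 on log2 values, the hybridisation controls as a covariate and CD133 high replicate 1 alone were chosen after seeing the data. No paired analysis was possible because the replicate numbers follow accession order and link no samples. The linear floors of 1 and 64 and log2(value + 32) were not run, since the values were already on the log2 scale, and Prom1 has no value with the dimmest 50% left out. Dim probe sets, listed at 0 in 1158 to 1297 cases per array, limit what can be measured near the bottom of the scale. Prom1 kept its direction and its side of the threshold in 18 of 18 alternatives (0.63 to 0.98), and Notch targets in 21 of 21. Where no reason is given below, the cause was not tested.

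Probe sets past the threshold (7 higher, 75 lower) numbered 12 and 152 with equal medians, 13 and 144 with equal 75th percentiles, 11 and 164 with the dimmest 50% left out (fewer were tested), 180 lower with the dimmest 25% left out, 1 and 6 with no variance trend, 13 and 172 with a robust variance trend, 2133 and 2675 with array weights, 25 and 170 at an adjusted p under 0.1, and 0 and 0 in the test without moderation. They numbered 31 lower with the floor of 5, and 0 and 0 (limma) with CD133 high replicate 1 alone, a single array assumed to vary like the CD133 low arrays. Leaving out 1 array gave 0 to 4277 higher and 0 to 5326 lower, the highest without CD133 high replicate 1, whose array weight was 0.248; each of the 82 kept its sign throughout.

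Gene lists past the threshold (2 higher, 9 lower) numbered, for those higher, 7 with quantile normalization, 5 with the dimmest 50% and 5 with the dimmest 25% left out, 1 with no variance trend, 1 with array weights, 1 with the mean of a gene's probe sets, 4 without _s_at and _x_at probe sets, 6 with the floor of 5, 14 with the covariate, 13 with CD133 high replicate 1 alone and 0 to 7 with 1 array left out. With an estimated correlation 0 were higher and 0 lower (camera; 2 at an unadjusted p under 0.05), and with fry 5 and 3. The Notch receptor and ligand list (median 0.14) passed at 0.19 with quantile normalization, 0.14 with the dimmest 25% left out, 0.22 without _s_at and _x_at probe sets, 0.14 with the floor of 5, 0.18 with the covariate and 0.17 with CD133 high replicate 1 alone, and its median ranged from 0.0708 to 0.18 with 1 array left out. The unfolded protein response list turned to 0.0219 with the covariate and to 0.0043 with CD133 high replicate 1 alone, where the pan-leukocyte list turned to 0.0415.

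Among single genes, directions turned only for those that had not passed. Dll3 turned to −0.0130 with quantile normalization, −0.0424 with equal medians, −0.00503 with array weights, −0.23 with the covariate and −0.12 with CD133 high replicate 1 alone, and ranged from −0.19 to 0.13 with 1 array left out. Heyl turned to −0.000162 with equal medians, −0.00354 with array weights and −0.24 with the mean of its probe sets, and ranged from −0.10 to 0.14 with 1 array left out. Notch3 turned to −0.0928 with the mean of its probe sets and to −0.28 without _s_at and _x_at probe sets. Hes5 stood at 0.00229 and 0.53 in these settings, but it was dim in both fractions and its direction was not measured. Notch1 turned to 0.10 and Nrarp to −0.0917 with the covariate, and with CD133 high replicate 1 alone Notch1 turned to 0.20, Nrarp to −0.0411 and Hey2 to −0.0668.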

Other observations

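The tests in this part were chosen only after the values were seen. Of 8 measured Gimap genes, which encode GTPases found mostly in lymphocytes, 4 fell, and 4 did not pass the threshold. The median difference over all 8 was −1.86, and no test of the group was run. Gimap6 changed by −2.76 (limma, adjusted p = 0.0408), Gimap4 by −2.10 (adjusted p = 0.0186), Gimap3 by −2.05 (adjusted p = 0.0186) and Gimap1 by −1.90 (adjusted p = 0.0204), while Gimap7, Gimap8, Gimap5 and Gimap9 differed by −1.81, −1.33, −0.57 and −0.10 (adjusted p = 0.0799, 0.0985, 0.44 and 0.776). All 8 lay lower under each of 3 scalings, with medians between −1.90 and −1.86.

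Probe sets of the same gene did not always move together. Of the 46 genes past the threshold, 27 have 1 probe set, and of the 19 with several, 5 had another past the threshold and 14 had none. In 7 of them another probe set had the opposite sign.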
